A study of Rattus norvegicus with 15 samples.

How the data were processed

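The deposited values were used as they stand. They are log2 intensities from robust multi-array average (RMA) normalization in Affymetrix Expression Console, per the labels, and the versions of that software and of the array annotation are not given in the sources used here. The labels name liver RNA taken with Trizol and then RNeasy columns, and biotin-labelled cRNA. Array medians ran from 7.11 to 7.24 on that scale, and 0 values were missing. All 15 arrays and all columns were kept. No raw intensities were read here, and no scan dates are in the labels, so array batches were not tested.

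The table has 29215 probe sets. A probe annotation supplied with the data names a gene for 15633 of them, 15310 with 1 symbol and 323 with several, and 13582 have no gene there. Probe sets with 1 symbol were kept. Where a gene had more than 1 probe set (527 genes) the 1 with the highest mean over all arrays was used, and 0 of these genes had probe sets called in opposite directions. This left 14506 genes, of which 14481 carry an identifier found in the RefSeq gene table (assembly GRCr8, used for names only), and 0 symbols were updated. Genes of near-identical families (Cyp2c, Cyp2b, Ugt2b, Sult2a, RT1, urinary proteins, Serpina3) may share probes. Unnamed probe sets are left out of all counts of genes.

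Group means over the 15 arrays were fitted with limma 3.58.1 in R 4.3.3, with variances moderated by eBayes without trend or robust options and 10 residual degrees of freedom. The contrasts were IPCR against control at day 21, IUCR against control, IPCR against control and IPCR against IUCR at day 450, control at day 450 against control at day 21, and the IPCR effect at day 450 minus that at day 21. A gene changed where its p, adjusted by Benjamini and Hochberg within a contrast over all 14506 genes, was below 0.05. Intensity is not a count of molecules, so log2 changes on arrays tend to understate large differences. No call of signal over background is in the files used here, and the lower quartile of the arrays was 6.00 to 6.16, so values near or below that may be background. SE is the moderated standard error from limma, and SD is that of 3 arrays. Values were said not to overlap where all 3 of 1 group lay beyond all 3 of the other, for which chance gives 10%; no such rule can be applied to the difference of 2 effects, so that comparison rests on limma alone.

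Gene lists were fixed before the data were examined: clock genes in a BMAL1 arm and a PER/DBP arm, clock modifiers, metabolic pathways, growth, stress and immune responses, sex-biased genes, liver zones and cell markers. Of 534 list members 474 are measured, and the other members are not analysed here. Arntl, G6pc, Pcx, Mt1a, Cyr61 and Ddx58 were matched to their current symbols Bmal1, G6pc1, Pc, Mt1, Ccn1 and Rig1, and Ndufs6 to Ndufs6-ps1, a match that is uncertain. The 36 lists with at least 3 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 36 lists. Each list was also tested with the correlation estimated from its own genes and with fry, a rotation test. Of all camera calls only those of 6 lists in the age comparison hold with an estimated correlation. Counts over the list alone adjust p over the members of that list.

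Genes were named by rule: the 10 largest rises and falls among passing genes whose groups do not overlap in each comparison of restricted with control rats, 5 of each in other comparisons, and the smallest p values where fewer than 5 passed. Clock genes, the 4 members with the smallest p of each called list and at most 2 passing members of other lists were added. Symbols that are only locus numbers and receptor families of smell and taste were not named.

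The alternatives chosen in advance were genes above the median level only, an estimated correlation, arrays centred on their median, quantile normalization, the replicate letter as a block, leaving out each array, only the groups compared, the mean of probe sets, fry, adjusted p below 0.10, and trend with robust moderation. The interquartile range of each array as a covariate was chosen after seeing the data. For each contrast the 3 against 3 arrays were also regrouped in all 10 ways, and for the 2 changes that share controls 100 draws without a group effect were simulated.

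On simulated data with 200 of 14506 genes changed between groups of 3, the method found 72.5% of changes of log2 0.5, 99.5% of log2 1 and 100% of log2 2. False calls were 2.68%, 5.24% and 1.48% of those made. The simulated noise was independent between genes and had no shifts shared by a whole array, so these rates may not hold for the real arrays. The labels say replicates are separate littermates, but not from how many litters, so p-values measure the spread between these samples and may not speak for other litters. Time of day at collection is not in the labels.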

Results

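Liver from 15 male Sprague-Dawley rats was measured on Affymetrix Rat Gene arrays, 1 array per rat, in 5 groups of 3. Mothers were fed freely (control), were restricted to 50% of calories in the second part of pregnancy (intrauterine calorie restriction, IUCR), or were restricted then and through suckling as well (intrauterine and postnatal calorie restriction, IPCR). Control and IPCR offspring were taken at day 21 and day 450, and IUCR offspring at day 450 only. After probe sets were reduced to named genes, 14506 genes were compared. Across genes, arrays of the same group correlated at r of 0.990 to 0.995 (15 pairs), arrays of different groups at the same age at 0.982 to 0.993 (36 pairs), and arrays of different ages at 0.961 to 0.981 (54 pairs). The first principal component held 53.5% of the variance and separated the ages, with day 21 arrays at -34.2 to -17.2 and day 450 arrays at 13.0 to 21.4. The second held 11.4%, with day 21 controls at -17.4, -15.7 and -16.8 and day 21 IPCR at 14.6, 14.6 and 4.96. With 3 arrays per group the median standard error of a log2 change was 0.0960, so small changes are measured with little precision. Clock genes are given for every comparison because the series concerns hepatic circadian cycling.

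At day 21 the liver of IPCR offspring differed from control in core clock genes, in sterol and fatty acid synthesis, in growth genes, and in antigen presentation and endothelial markers. Bmal1, the activator at the centre of the clock, was lower (log2 change -2.07, standard error (SE) 0.23, limma adjusted p = 5.13e-05, 3 against 3 arrays), at 6.89 (SD 0.40) against 8.97 (SD 0.05). Dbp, a clock output driven by BMAL1 and CLOCK, was 4.56-fold higher (2.19, SE 0.21). Sds, which breaks down serine for glucose production, was 11.5-fold higher (3.52, SE 0.40), at 11.10 (SD 0.57) against 7.58 (SD 0.34). Cyp51, an enzyme of cholesterol synthesis, fell by 2.58 (SE 0.41). Igfbp2, a binding protein for insulin-like growth factors that rises in fasting, was 10.4-fold higher (3.38, SE 0.22), and Igfals, which holds circulating IGF1 in its ternary complex, was 4.93-fold lower (-2.30, SE 0.13).

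The 2 arms of the clock moved in opposite directions. Of 12 measured genes in the PER/DBP arm, 10 rose and 0 fell (median log2 change 0.76, camera adjusted p = 3.89e-12; adjusted p = 0.117 with an estimated correlation), and 10 rose when p was adjusted over the list alone. Per3 rose by 2.24 (SE 0.23), Per1 by 1.35 (SE 0.14), Per2 by 1.09 (SE 0.21) and Tef by 0.83 (SE 0.12). Nr1d2 rose by 0.66 (SE 0.09), Usp2 by 1.04 (SE 0.20) and Nr1d1, the repressor of Bmal1, by 0.64 (SE 0.15). Of 5 genes in the BMAL1 arm, 4 fell and 0 rose (median -0.55, adjusted p = 0.00151; adjusted p = 0.117 with an estimated correlation), with the same 4 over the list alone. Npas2, a partner of BMAL1, fell by 1.28 (SE 0.22) and Clock, the other partner, by 0.42 (SE 0.10). Nfil3, which represses DBP targets, fell by 0.55 (SE 0.13), while Cry1 did not pass (0.22, SE 0.11, adjusted p = 0.239). Wee1 rose by 0.70 (SE 0.18) and Cry2 by 0.41 (SE 0.11), and Bhlhe40 (0.12, SE 0.24) and Bhlhe41 (0.11, SE 0.16) did not pass. The smaller clock changes depend on single arrays. Clock is lost without control B, IPCR A or IPCR B (adjusted p 0.0521 to 0.0642), Nfil3 without control A, control C or IPCR A (0.0583 to 0.0945) and under quantile normalization, and Nr1d1 without IPCR B (0.0735). Wee1 is lost without any array except IPCR B (0.0540 to 0.0790) and Cry2 without any of the 6 (0.0595 to 0.109).

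**Figure D1:**
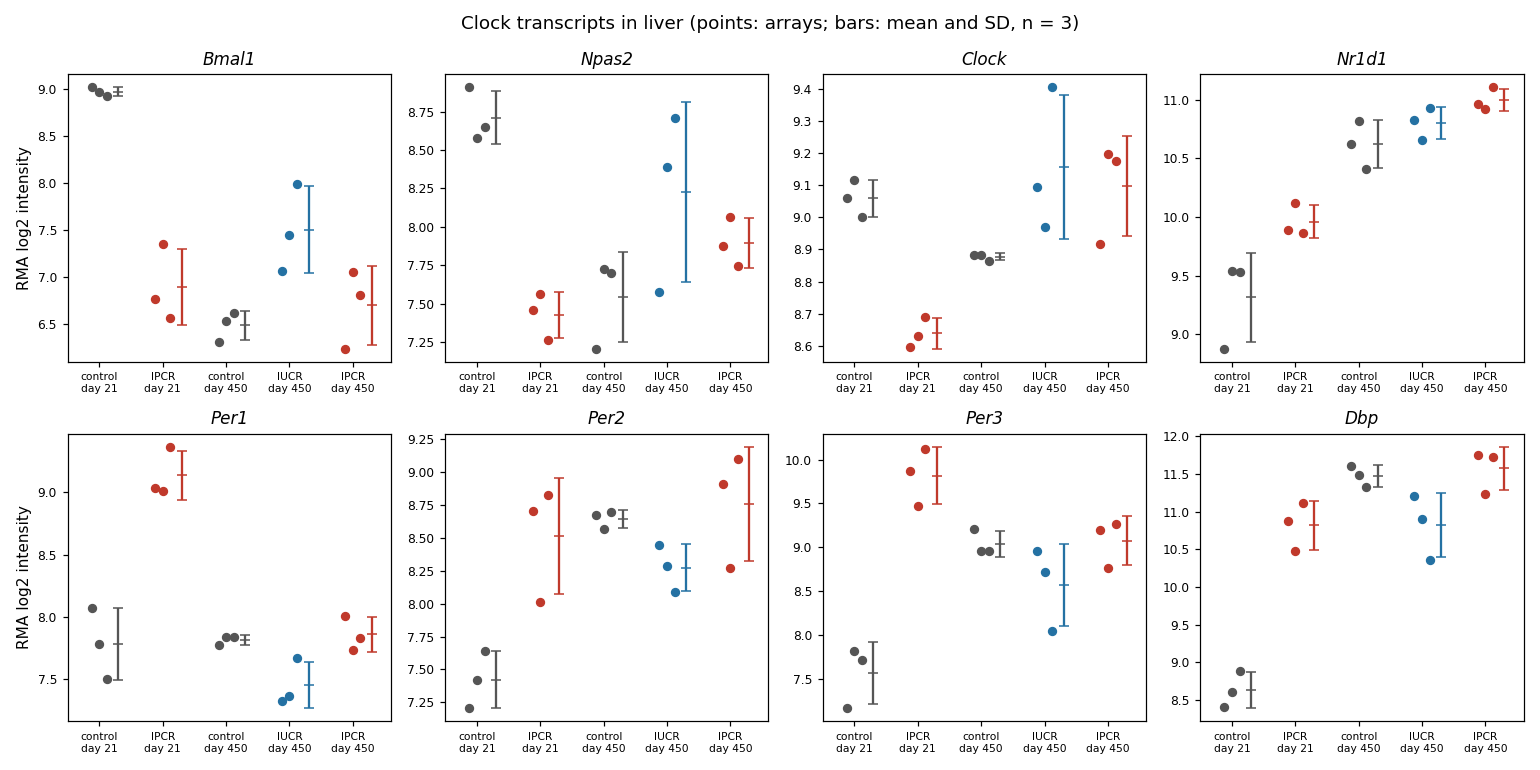
Points are single arrays and bars the group mean with SD, as RMA log2 intensity, for 8 clock genes in the 5 groups. Bmal1 and Npas2 are lower and Dbp and Per3 higher in day 21 IPCR than in day 21 control, and the day 450 groups lie closer together.

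Cholesterol synthesis fell almost as a whole. Of 20 measured genes 18 fell and 0 rose (median -1.34, adjusted p = 1.13e-18; adjusted p = 0.277 with an estimated correlation), and the list alone gives the same 18. Dhcr7 fell by 2.17 (SE 0.31), Tm7sf2 by 1.82 (SE 0.20), Fdft1 by 1.51 (SE 0.23) and Ebp by 1.17 (SE 0.15). Msmo1 fell by 2.49 (SE 0.47) and Idi1, an early isoprenoid enzyme, by 2.39 (SE 0.44). Fatty acid synthesis fell with it, in 12 of 19 genes with 0 rising (median -0.94, adjusted p = 4.21e-11; adjusted p = 0.277 with an estimated correlation), and 16 fell over the list alone. Acss2, which makes acetyl-CoA from acetate, fell by 2.26 (SE 0.26), Thrsp, a lipogenic response gene, by 2.36 (SE 0.34), Fads1 by 1.61 (SE 0.25) and Gpam by 1.38 (SE 0.22). The fall was uneven between rats. The mean change of the cholesterol list from control was -1.84, -1.66 and -0.58 on IPCR arrays A, B and C, and of the fatty acid list -1.27, -1.25 and -0.54. Lpl, the lipoprotein lipase that is high in fetal and suckling liver, was 9.21-fold higher (3.20, SE 0.19).

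The growth hormone and IGF list fell in 5 of 12 genes with 1 rising (median -0.42, adjusted p = 0.00799; adjusted p = 0.277 with an estimated correlation), or 6 and 2 over the list alone. Ghr, the growth hormone receptor, fell by 0.97 (SE 0.10) and Igf1, its main liver target, by 0.92 (SE 0.10). Afp, a fetal gene normally silenced after birth, was 5.30-fold higher (2.41, SE 0.20), and H19, an imprinted RNA, rose by 1.57 (SE 0.19). In the fetal and imprinted list 3 of 13 rose and 1 fell (median 0.17, adjusted p = 0.00799; adjusted p = 0.376 with an estimated correlation), or 4 and 1 over the list alone. Igf2bp1 rose by 0.48 (SE 0.09), and Mest, an imprinted growth gene, fell by 0.64 (SE 0.10).

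Among the largest changes outside these lists, Noct, a clock-driven deadenylase-family gene, rose by 3.14 (SE 0.34), Got1, an aspartate transaminase, by 2.18 (SE 0.25), Upp2 by 2.13 (SE 0.43) and Wsb1 by 1.83 (SE 0.24). Nrep fell by 2.49 (SE 0.11, adjusted p = 8.53e-09), as did Pigr, the carrier of immunoglobulin A into bile (-2.86, SE 0.21), Akr1b7 (-2.86, SE 0.45) and Arrdc3 (-2.72, SE 0.17). Sult2a1, a sulfotransferase with close paralogues that the probes may not separate, fell by 3.08 (SE 0.56). None of the 20 largest changes is lost when any 1 array is left out.

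**Figure D2:**
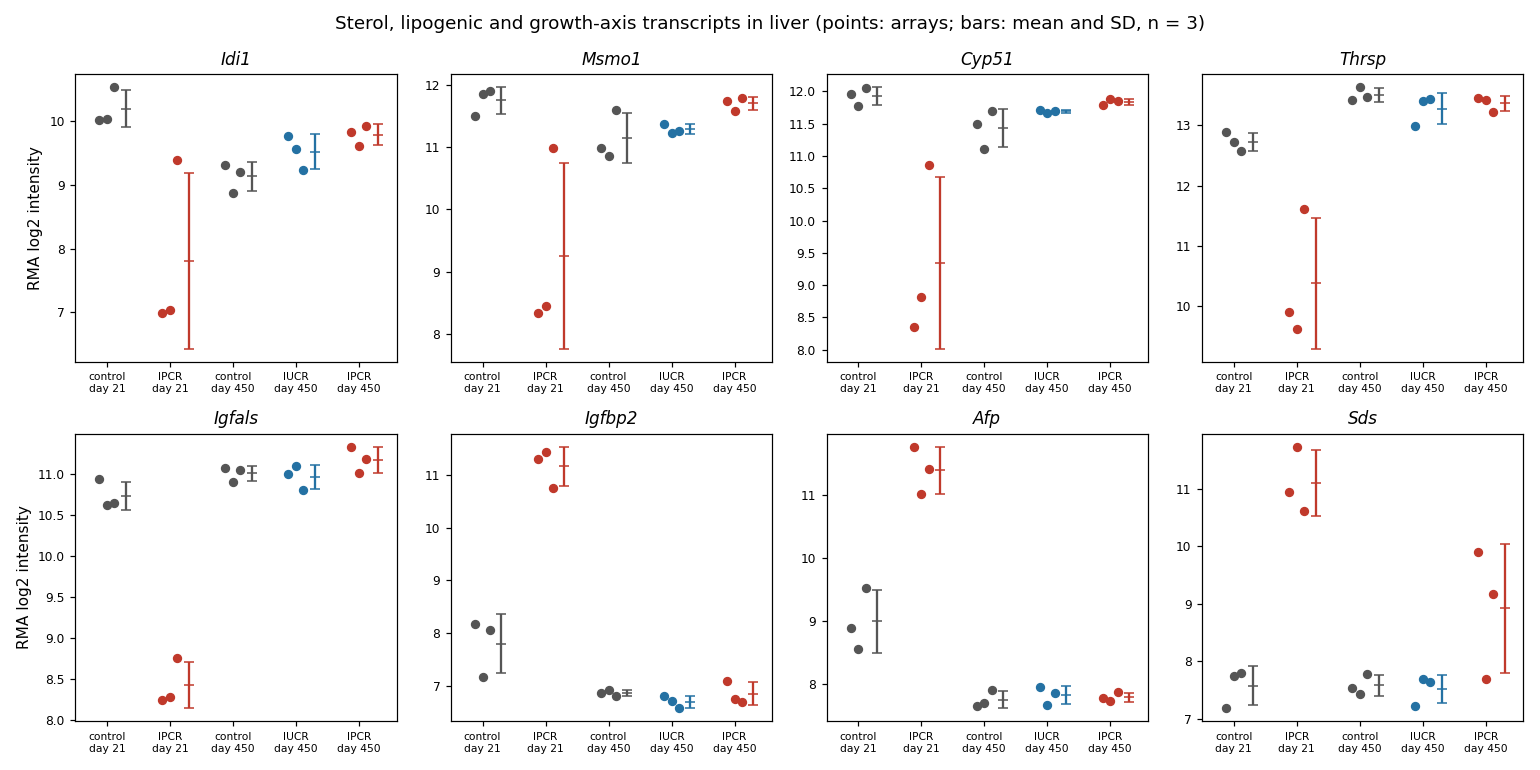
Points are single arrays and bars the group mean with SD, as RMA log2 intensity, for 8 metabolic and growth genes in the 5 groups. Idi1, Msmo1, Cyp51, Thrsp and Igfals are lower and Igfbp2, Afp and Sds higher in day 21 IPCR than in day 21 control.

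Antigen presentation fell in 8 of 15 genes with 0 rising (median -0.46, adjusted p = 2.91e-07; adjusted p = 0.277 with an estimated correlation), or 10 over the list alone. Psmb9 fell by 1.30 (SE 0.15) and Psmb8 by 1.12 (SE 0.14), both immunoproteasome subunits, with B2m down by 0.71 (SE 0.10) and Tap2 by 0.46 (SE 0.09). Endothelial markers fell in 4 of 7 (median -0.51, adjusted p = 4.27e-05; adjusted p = 0.376 with an estimated correlation), or all 7 over the list alone. On IPCR arrays A, B and C the mean change of the list from control was -0.22, -0.72 and -0.50. Control A stood at -0.22, level with IPCR A, and controls B and C at 0.14 and 0.08, so the groups meet. Kdr, a receptor for VEGF, fell by 0.65 (SE 0.14), Fcgr2b by 0.82 (SE 0.18), Eng by 0.51 (SE 0.12) and Tek by 0.34 (SE 0.10). Without control B or IPCR B the calls of Kdr (0.0505 and 0.0506), Fcgr2b (0.0545 and 0.0553) and Eng (0.0576 to 0.0738) are lost, and Tek is lost without any of 4 arrays (0.0906 to 0.179). Macrophage markers were lower as a list (median -0.26, adjusted p = 0.0117; adjusted p = 0.814 with an estimated correlation) with 0 of 11 genes passing. That list is lost without control B (0.163), control C (0.0854) or IPCR B (0.0608) and under quantile normalization (-0.14, 0.133).

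Bile acid and sterol transport genes fell in 7 of 17 with 1 rising (median -0.16, adjusted p = 0.00799; adjusted p = 0.376 with an estimated correlation), the same 7 and 1 over the list alone, and under quantile normalization the list does not pass (adjusted p = 0.0548). Slco1b2, a bile acid uptake carrier, fell by 1.02 (SE 0.12), Nr1h4, the bile acid receptor FXR, by 0.77 (SE 0.13) and Hsd3b7 by 1.03 (SE 0.18). Oxidative phosphorylation was slightly higher as a list, with 2 of 28 rising (median 0.09, adjusted p = 0.00799; adjusted p = 0.814 with an estimated correlation) and the same 2 over the list alone. Cox4i1 rose by 0.30 (SE 0.06) and Ndufb8 by 0.35 (SE 0.10), the latter lost without any of 5 arrays (0.0675 to 0.127). Periportal genes rose in 4 of 10 and fell in 2 (median 0.36, adjusted p = 0.0445; adjusted p = 0.575 with an estimated correlation), or 5 and 2 over the list alone. Gls2 rose by 0.90 (SE 0.20) and Arg1, the last enzyme of the urea cycle, by 0.71 (SE 0.10), while Ctsc fell by 0.86 (SE 0.09). The periportal list is lost without control C (0.104), IPCR B (0.105) or IPCR C (0.0533).

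Lists not called at day 21 still held single genes. Gluconeogenesis had 5 rising and 2 falling (median 0.18), with Tat 2.83-fold higher and Gys2, the liver glycogen synthase, up by 0.80. Xenobiotic metabolism had 6 rising and 2 falling (median -0.09), or 6 and 6 over the list alone, with Por at 1.19 and Cyp2b3 at -1.42. Fatty acid oxidation had 1 rising and 7 falling (median 0.09), among them Pdk4 (-1.37) and Bdh1 (-0.65). Glucocorticoid targets had a median of 0.26 (1 rose and 2 fell, or 4 and 3 over the list alone), pericentral genes -0.17 (0 rose, 4 fell), the amino acid response -0.02, acute phase -0.10, heat shock -0.03, the unfolded protein response -0.11, immediate early genes -0.09 and interferon response -0.12. Cell cycle stood at -0.27, clock modifiers at -0.04, female-biased genes at -0.28 and male-biased genes at 0.07. Cell markers not called were those of hepatocytes (0.11), cholangiocytes (0.03), stellate cells (-0.02), T and NK cells (0.02), B cells (-0.05), neutrophils (0.03), red cell precursors (-0.15), adipocytes (0.03) and pancreatic acinar cells (0.03). The median and the mean or test differ in sign for clock modifiers, fatty acid oxidation, male-biased genes, T and NK cells, xenobiotic metabolism and adipocytes.

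In all, 1396 genes changed at day 21, 382 higher and 1014 lower, and 143 of them by more than 2-fold (39 higher, 104 lower). The direction depends on scaling: 27.4% were higher as deposited, and after quantile normalization 1624 genes passed with 783 higher and 841 lower (48.2%), 1122 of them shared. The 3 IPCR and 3 control values did not overlap for 4341 genes (29.9%), where chance would give 10%. Of 12 lists past camera, 0 hold with an estimated correlation and 9 pass fry in 1 direction, without oxidative phosphorylation, macrophage and periportal (adjusted p = 0.0694) genes. Here fry asks whether the genes of a list move on balance 1 way, or in its mixed form whether they change in either direction, and neither form compares them with other genes. Without control B 832 genes passed, without IPCR A 755 and without IPCR B 779. When only genes above the median level were kept, 8 of the 12 lists stayed called.

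At day 450 no gene passed for IUCR offspring against control, and 11 lists passed camera with small medians, of which 0 hold with an estimated correlation and 0 pass fry. Ptprt had the smallest p (-0.72, SE 0.12, adjusted p = 0.311, 3 against 3 arrays), with Coq8a, a kinase-like gene of coenzyme Q synthesis, at 0.63 (SE 0.11), and neither passed. Bmal1 stood at 1.02 (SE 0.23, adjusted p = 0.460) and Dbp at -0.65 (SE 0.21), also without passing. The BMAL1 list was higher (median 0.30, adjusted p = 0.00470; adjusted p = 0.233 with an estimated correlation), with 0 of 5 passing over all genes and 4 higher with 1 lower over the list alone. The PER/DBP list was lower (median -0.30, adjusted p = 7.04e-05; adjusted p = 0.466 with an estimated correlation), with 0 of 12 passing and 2 lower over the list alone.

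None of the other clock genes passed in IUCR: Npas2 0.68, Clock 0.28, Nfil3 0.30, Cry1 -0.29, Wee1 -0.76 (SE 0.18), Per1 -0.36, Per2 -0.37, Per3 -0.47, Nr1d1 0.18, Nr1d2 -0.10, Tef -0.16, Usp2 -0.42, Cry2 -0.24, Bhlhe40 -0.22 and Bhlhe41 -0.18. The mean change of the PER/DBP list from control was -0.16, -0.34 and -0.43 on IUCR arrays A, B and C, and that of the BMAL1 list 0.15, 0.45 and 0.59. Collection times are not in the labels, so a different time of day at collection cannot be told apart from an effect of restriction here. Other genes with small p values were Pnkd (0.62), Slc45a3 (0.52), Pkdcc (0.52) and Fzd4 (0.48) on the higher side and Acbd7 (-0.51), Jchain (-0.73), Hoxd1 (-0.35) and Hdc, the histidine decarboxylase that makes histamine (-0.49), on the lower side. Array IUCR B stood apart in some sex-biased genes. Male-biased Hsd3b5 was 9.363 there, against 12.412 and 12.334 on IUCR A and C, and female-biased Cyp2c12 12.014, against 8.982 and 9.84. Male-biased Rup2 (12.975) stayed near its control range (12.978 to 13.115). The cause was not tested.

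The other lists past camera in IUCR held no gene passing on its own. Oxidative phosphorylation was higher (0.12, adjusted p = 1.86e-06; adjusted p = 0.545 with an estimated correlation), as were pericentral genes (0.30, 0.00149; adjusted p = 0.466 with an estimated correlation), xenobiotic metabolism (0.16, 0.00125; adjusted p = 0.482 with an estimated correlation) and interferon response (0.19, 0.00191; adjusted p = 0.545 with an estimated correlation). Periportal genes (0.12, 0.0147; adjusted p = 0.482 with an estimated correlation) and glucocorticoid targets (0.13, 0.0468; adjusted p = 0.658 with an estimated correlation) were higher, each with 1 gene over the list alone. Cholesterol synthesis was higher (0.14, 0.0215; adjusted p = 0.820 with an estimated correlation). B cell markers (-0.13, 0.0147; adjusted p = 0.240 with an estimated correlation), with 1 gene over the list alone, and neutrophil markers (-0.12, 0.0308; adjusted p = 0.466 with an estimated correlation) were lower. Both lists hold members dim enough to be background, such as Jchain (5.422 to 5.611 in IUCR) and S100a8 (3.833 to 4.162). The median and the mean or test differ in sign for clock modifiers, red cell precursors and T and NK cells.

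With limma 0 genes passed in IUCR, 1052 had p below 0.05 before adjustment, 0 passed at adjusted p below 0.10, and 2 passed without control B. The 3 IUCR and 3 control values did not overlap for 1621 genes (11.2%), where chance would give 10%. Of 11 lists past camera, 0 pass fry in either form and 3 hold without each array: BMAL1, PER/DBP and oxidative phosphorylation, the last lost under quantile normalization (0.03, adjusted p = 0.105) and BMAL1 among genes above the median level (adjusted p = 0.0520). Without control A 6 lists are lost: cholesterol, interferon, B cell, neutrophil, pericentral and periportal (0.0693 to 0.227). Cholesterol and neutrophil are lost without control B (0.0612 to 0.119), glucocorticoid, neutrophil and xenobiotic without control C (0.0652 to 0.407), glucocorticoid and neutrophil without IUCR A (up to 0.0783), cholesterol without IUCR B (0.103), and glucocorticoid and periportal without IUCR C (0.123 to 0.173).

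IPCR offspring at day 450 differed from control in 5 genes, against 3 under quantile normalization, 2 with only the groups compared and 0 with the spread of each array as a covariate. Arrays centred on their median gave 14 genes, trend with robust moderation 15, genes above the median level only 17, and the replicate letter as a block 0. Ugt2b1, a glucuronosyltransferase with close paralogues, was 1.87-fold higher (0.90, SE 0.13, adjusted p = 0.0255, 3 against 3 arrays), Cxcl14, a chemokine, 1.86-fold (0.90, SE 0.12) and Med14, a subunit of the Mediator complex, differed by 0.71 (SE 0.11) at levels low enough to be background (5.68 against 4.97). Ltc4s, which makes leukotriene C4, was 2.68-fold lower (-1.42, SE 0.22, adjusted p = 0.0317) and Pmm1 1.54-fold lower (-0.62, SE 0.09). No clock list or gene passed: the BMAL1 list had a median of 0.22 (adjusted p = 0.0571) and the PER/DBP list 0.11 (adjusted p = 0.344), with Bmal1 at 0.21 (SE 0.23), Dbp 0.10 (SE 0.21), Per1 0.04, Per2 0.12, Per3 0.03, Nr1d1 0.38, Cry1 0.29 and Bhlhe41 0.54.

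Several metabolic lists were higher at day 450 IPCR, mostly without single genes passing. Gluconeogenesis (0.16, adjusted p = 0.00114; adjusted p = 0.476 with an estimated correlation) had 4 higher over the list alone, and periportal genes (0.28, 0.00252; adjusted p = 0.343 with an estimated correlation) had 5. Some members differed between rats. On IPCR arrays A, B and C Sds stood at 9.897, 7.696 and 9.175, against 7.435 to 7.784 in control. Gls2 stood at 11.615, 10.66 and 11.57, against 10.687 to 10.794. Gpt, of the gluconeogenesis list, was above control on each of them (10.328, 9.663 and 10.579 against 8.844 to 9.351). Xenobiotic metabolism (0.19, 0.0107; adjusted p = 0.476 with an estimated correlation) held 1 passing gene, Ugt2b1. Bile acid genes (0.12, 0.0212; adjusted p = 0.476 with an estimated correlation) had 3 higher and cholesterol synthesis (0.24, 0.0212; adjusted p = 0.721 with an estimated correlation) 1 higher over the list alone. Oxidative phosphorylation (0.11, 0.00201; adjusted p = 0.683 with an estimated correlation), pericentral genes (0.26, 0.0130; adjusted p = 0.476 with an estimated correlation) and the unfolded protein response (0.14, 0.0212; adjusted p = 0.683 with an estimated correlation) were higher too. Pancreatic acinar markers were higher (0.54, 0.0321; adjusted p = 0.683 with an estimated correlation), and all 9 were highest on array IPCR C.

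Acute phase genes were lower (-0.19, adjusted p = 0.00114; adjusted p = 0.476 with an estimated correlation), with 1 over the list alone. Immediate early genes (-0.13, 0.0212; adjusted p = 0.476 with an estimated correlation) had 3 lower over the list alone, and Junb stood at -0.53 without passing. Markers were lower for neutrophils (-0.18, 0.0104; adjusted p = 0.236 with an estimated correlation), cholangiocytes (-0.26, 0.0107; adjusted p = 0.476 with an estimated correlation), adipocytes (-0.14, 0.0130; adjusted p = 0.236 with an estimated correlation), B cells (-0.14, 0.0136; adjusted p = 0.236 with an estimated correlation) and macrophages (-0.15, 0.0238; adjusted p = 0.683 with an estimated correlation). Some neutrophil, cholangiocyte and B cell markers are dim enough to be background. In day 450 IPCR S100a8 stood at 3.848 to 4.143, Cldn7 at 5.377 to 5.753 and Ms4a1 at 5.111 to 5.253. Such dim members also enter the other comparisons of these lists. The median and the mean or test differ in sign for female-biased genes, the growth hormone list, interferon response, fatty acid synthesis and T and NK cells. Of 16 lists past camera 0 hold with an estimated correlation, 1 passes fry in 1 direction (adipocyte, 0.0189) and 2 in its mixed form (gluconeogenesis and immediate early, both 0.0339).

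With limma 2143 genes had p below 0.05 before adjustment and 69 passed at adjusted p below 0.10. The 3 IPCR and 3 control values did not overlap for 2574 genes (17.7%), where chance would give 10%. The 5 genes are each lost without 4 or 5 of the 6 arrays (0.0561 to 0.182), and Pmm1 also as the mean of its probe sets (-0.35, adjusted p = 0.120). The count was 0 without control A, IPCR A or IPCR C, 3 without control B or control C, and 80 without IPCR B. None of the 5 genes is among those called without control B, and only Cxcl14 is among those called without control C. Gluconeogenesis, neutrophil and periportal lists hold without each array. Without control A 7 lists are lost (acute phase, cholesterol, adipocyte, B cell, macrophage, acinar, pericentral; 0.0512 to 0.544), and 5 without control B (cholesterol, immediate early, cholangiocyte, acinar, unfolded protein; 0.0719 to 0.145). Without control C 3 are lost (bile acid, oxidative phosphorylation, xenobiotic; 0.142 to 0.449), and 2 without IPCR A (macrophage, unfolded protein; 0.139 to 0.459). Without IPCR C bile acid, pericentral and unfolded protein lists are lost (up to 0.0912) and the acinar list turns to -0.09 (adjusted p = 0.0113). Under quantile normalization oxidative phosphorylation (-0.01) and the unfolded protein response (0.01) have medians near 0.

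**Figure D3:**
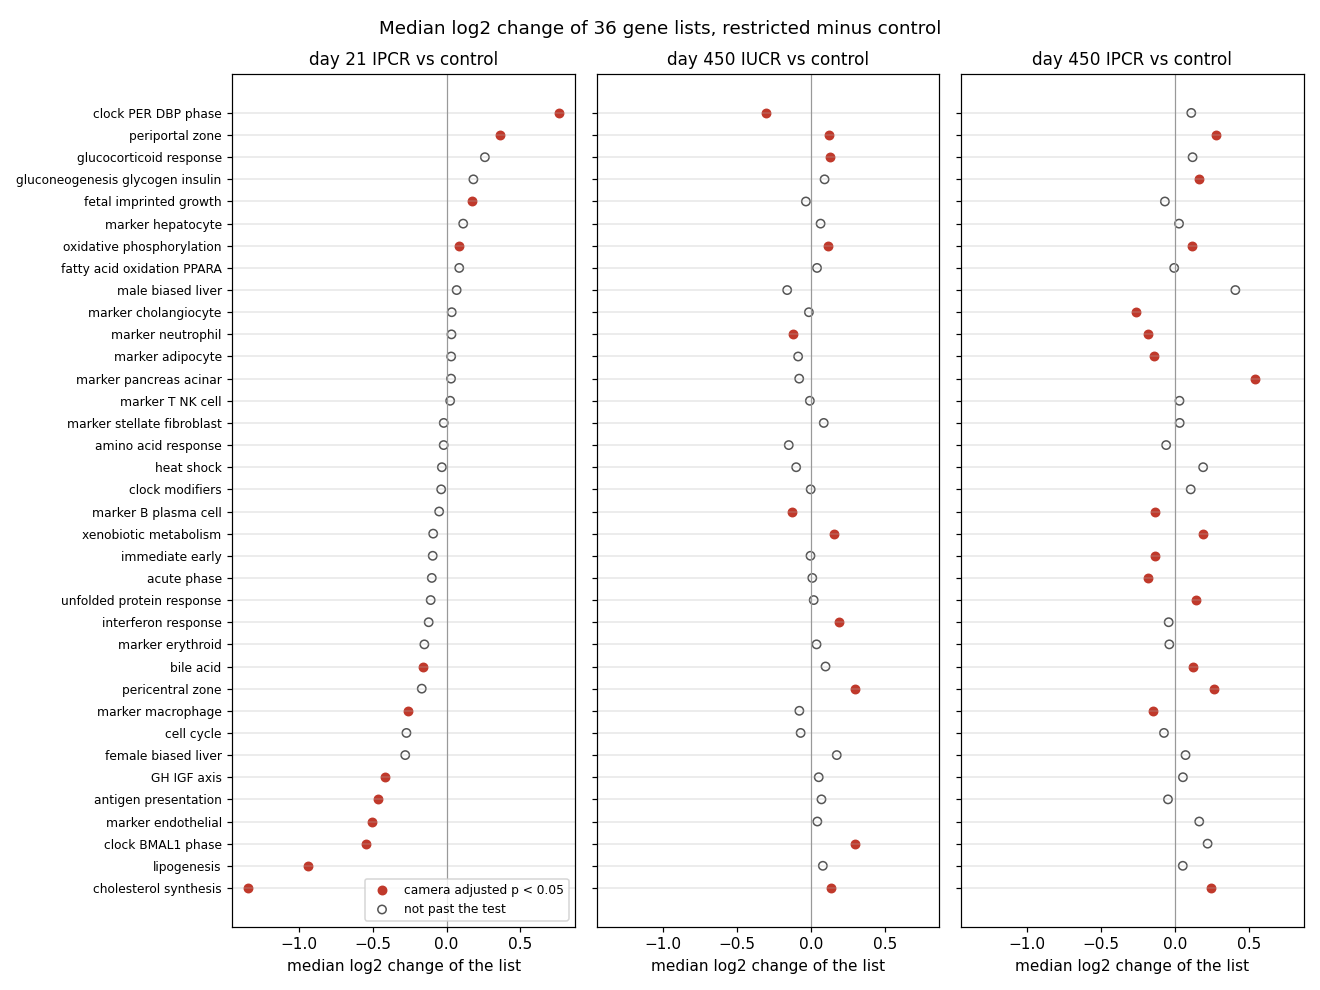
Each point is the median log2 change of 1 of 36 gene lists, in panels for day 21 IPCR, day 450 IUCR and day 450 IPCR against control of the same age, filled red where camera adjusted p was below 0.05. The day 21 changes of the cholesterol, fatty acid and PER/DBP lists are larger than any change at day 450.

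No relation of the IUCR and IPCR changes at day 450 is shown beyond that of the 3 control arrays they share. Across 14506 genes they correlated at r = 0.573, inside the range of a simulation with shared controls and no group effect (median 0.507, range -0.165 to 0.858, 100 draws). They had the same sign in 72.6% of genes (simulated median 66.7%, range 43.7 to 81.6%), and the covariance was 0.0133 (simulated median 0.00758, range -0.000977 to 0.0181). The 3 controls cannot be split into parts of at least 2 arrays, so part of the correlation may come from the shared arrays, and r ran from 0.448 to 0.669 when single arrays were left out.

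Compared directly at day 450, IPCR and IUCR differed in 6 genes, against 0 under quantile normalization, 0 with only the groups compared and 1 with trend and robust moderation. Cyp7a1, the first enzyme of bile acid synthesis and a clock output, was 3.71-fold higher in IPCR (1.89, SE 0.25, adjusted p = 0.0243, 3 against 3 arrays). Zfp189 (1.11, SE 0.18), Gstm3, a glutathione transferase (1.04, SE 0.17), Cxcl14 (0.86, SE 0.12) and Pus3 (0.52, SE 0.08) were higher, and Apol3l1 was lower (-1.16, SE 0.18). The PER/DBP list was higher in IPCR (median 0.44, adjusted p = 1.54e-07; adjusted p = 0.440 with an estimated correlation), with 0 genes passing and 7 over the list alone. Dbp (0.75), Bhlhe41 (0.72), Cry1 (0.59) and Bmal1 (-0.80) did not pass. The mean change of the PER/DBP list from control was 0.21, -0.14 and 0.23 on IPCR arrays A, B and C. On IUCR arrays A, B and C it was -0.16, -0.34 and -0.43, so IPCR B and IUCR A nearly meet. A different time of day at collection could also move this list, and collection times are not in the labels.

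Heat shock genes were higher in IPCR (0.27, adjusted p = 5.36e-04; adjusted p = 0.440 with an estimated correlation), with 5 higher and 1 lower over the list alone, as were gluconeogenesis (0.15, 0.0152; adjusted p = 0.619 with an estimated correlation), with 2 higher over the list alone, the unfolded protein response (0.10, 0.0353; adjusted p = 0.777 with an estimated correlation) and acinar markers (0.67, 5.46e-04; adjusted p = 0.619 with an estimated correlation). Lower were acute phase (-0.15, 3.61e-06; adjusted p = 0.440 with an estimated correlation), interferon response (-0.18, 2.39e-05; adjusted p = 0.460 with an estimated correlation), antigen presentation (-0.12, 0.00141; adjusted p = 0.619 with an estimated correlation) and cholangiocyte markers (-0.16, 0.00141; adjusted p = 0.440 with an estimated correlation). Immediate early genes were lower (-0.15, 0.0241; adjusted p = 0.619 with an estimated correlation), with 2 over the list alone. The median and the mean or test differ in sign for cell cycle, B cells, stellate cells, T and NK cells, oxidative phosphorylation, pericentral and xenobiotic genes. Of 10 lists past camera 0 pass fry in 1 direction and 4 in its mixed form.

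With limma 1084 genes had p below 0.05 before adjustment, 10 passed at adjusted p below 0.10, and values did not overlap for 1620 genes (11.2%), where chance would give 10%. Each of the 6 genes is lost without 3 to 5 of the arrays (0.0542 to 0.250), Cyp7a1 without IUCR C, IPCR A or IPCR C (0.0642 to 0.189). The count was 2 without IUCR B, 0 without IUCR C, IPCR A or IPCR C, and 14 without IPCR B. Acute phase, antigen presentation, PER/DBP and heat shock lists hold without each array. Gluconeogenesis and immediate early are lost without IUCR B (0.319 to 0.629), cholangiocyte and unfolded protein without IUCR C (0.191 to 0.664), interferon and unfolded protein without IPCR A (up to 0.267), and immediate early, unfolded protein and acinar (0.02) without IPCR C (0.124 to 0.993).

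In control liver male-biased genes of steroid and drug metabolism were higher at day 450 than at day 21. Hsd3b5, a male-biased steroid reductase gene, was higher at day 450 (6.39, SE 0.55, adjusted p = 1.89e-06, 3 against 3 arrays), at 11.93 against 5.53. Cyp2c13 (6.13, SE 0.31) and Cyp2c11 (6.11, SE 0.39), cytochromes of adult males from a family of near-identical sequences, rose, as did Cyp2a2 (4.67, SE 0.60) and Rup2, a urinary protein from another family of near-identical members (6.38, SE 0.23). The day 21 mean of Hsd3b5 lies below the lower quartile of the arrays and may be background, and those of the other 4 (6.46 to 6.84) are not far above it, so the sizes of these rises are uncertain. Cyp17a1, a steroid hydroxylase, was 16.8-fold lower (-4.07, SE 0.32) and A2m, an acute phase protein of fetal and young rats, 11.7-fold lower (-3.55, SE 0.27), with Akr1b7 (-3.79, to a level of 5.93 that may be background), Cyp2b2 (-3.56) and Alox15 (-3.30). Bmal1 was lower (-2.48, SE 0.23) and Dbp 7.16-fold higher (2.84, SE 0.21), the direction seen for IPCR at day 21, and both comparisons use the same 3 day 21 control arrays.

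Male-biased genes rose in 7 of 8 (median 5.39, adjusted p = 1.13e-13) and female-biased genes fell in 4 of 4 (-0.94, 3.36e-05; adjusted p = 0.0578 with an estimated correlation), among them Cyp2c12 (-3.11, SE 0.60). Cell cycle genes fell in 24 of 29 (-0.72, 3.94e-22; adjusted p = 0.0745 with an estimated correlation), or 27 over the list alone, with Top2a down by 1.78 (SE 0.17). Interferon response rose in 14 of 19 (1.10, 9.32e-18), with Usp18 up by 2.91 (SE 0.22), Mx2 by 2.75 (SE 0.27) and Oas1a by 2.34 (SE 0.21). At day 21 Usp18 (4.86) and Oas1a (6.31) are dim enough to be background, so the sizes of those rises are uncertain. In the PER/DBP list 9 of 12 rose, or 10 over the list alone (0.90, 7.31e-12), and in the BMAL1 list 3 of 5 fell, or 4 over the list alone (-0.44, 5.65e-05). Per3 rose by 1.47, Nr1d1 by 1.30, Per2 by 1.22, Nr1d2 by 0.95 and Tef by 0.82, and Npas2 fell by 1.17. Bhlhe40 rose by 0.96 but is lost without day 21 control B or day 450 control B (0.0853 and 0.0898), and Nfil3 fell by 0.44 but is lost without any of 4 arrays (0.127 to 0.184). Of the 4 female-biased genes A1bg is lost without any of 5 arrays (limma adjusted p 0.0528 to 0.216). Per1 (0.03), Clock (-0.18), Cry1 (-0.26), Usp2 (0.46) and Wee1 (0.38) did not pass.

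Pericentral genes fell in 8 of 10, or 9 over the list alone (-0.79, adjusted p = 3.45e-11), with Slc13a3 down by 1.86 and Cyp1a2 by 1.68. Stellate markers fell in 5 of 11, or 7 over the list alone (-0.50, 1.08e-07), among them Col3a1, a fibrillar collagen (-1.71, SE 0.12). Fetal and imprinted genes fell in 5 of 13 with 0 rising, or 7 and 1 over the list alone (-0.25, 4.18e-05; adjusted p = 0.0815 with an estimated correlation), with H19 down by 2.83 (SE 0.19) and Mest by 1.47 (SE 0.10). Heat shock genes rose in 7 of 11, or 8 with 1 falling over the list alone (0.54, 2.95e-05; adjusted p = 0.112 with an estimated correlation). Bile acid genes fell in 5 of 17 with 1 rising, or 7 and 1 over the list alone (-0.32, 9.59e-05; adjusted p = 0.112 with an estimated correlation), with Abcg5, a sterol exporter, down by 2.12 (SE 0.16). Fatty acid oxidation rose in 9 of 29 with 1 falling, or 12 and 1 over the list alone (0.23, 1.9e-04; adjusted p = 0.324 with an estimated correlation), with Cpt1a up by 0.63. Red cell precursor genes fell in 2 of 8, or 3 over the list alone (-0.48, 5.74e-04; adjusted p = 0.258 with an estimated correlation). Cholesterol synthesis was lower with 0 of 20 passing (-0.35, 1.08e-04; adjusted p = 0.520 with an estimated correlation). Antigen presentation was higher with 4 of 15 rising (0.16, 0.00536; adjusted p = 0.514 with an estimated correlation), but not without day 21 control A (-0.03, 0.311). Xenobiotic metabolism fell in 9 of 23 with 2 rising, or 10 and 4 over the list alone (-0.12, 0.00193; adjusted p = 0.324 with an estimated correlation), and oxidative phosphorylation in 2 of 28, or 0 over the list alone (-0.13, 0.00113; adjusted p = 0.590 with an estimated correlation). Both are lost without day 450 control C (0.0837 to 0.103).

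With age 1434 genes changed, 677 higher and 757 lower, 216 by more than 2-fold (107 higher, 109 lower), and 28.0% of genes did not overlap, where chance would give 10%. Of 17 lists past camera 6 hold with an estimated correlation: stellate (0.0280), BMAL1 (0.0280), interferon (0.0369), pericentral (0.0369), male-biased (0.0431) and PER/DBP (0.0451), and 16 pass fry in 1 direction. The median and the mean or test differ in sign for acute phase, clock modifiers, hepatocytes, macrophages, acinar cells and periportal genes.

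The effect of IPCR at day 450 differed from that at day 21 in the clock, in lipid synthesis and in growth genes. Maternal restriction in IPCR ran to postnatal day 21, so day 21 rats were taken as it ended and day 450 rats long after. Age and time since restriction therefore cannot be told apart in this comparison. Nrep, which fell at day 21, showed a difference of 3.05 (SE 0.16, adjusted p = 7.06e-08, 12 arrays), and Igfbp2 and Lpl, which rose at day 21, differences of -3.39 (SE 0.31) and -3.00 (SE 0.27). Bmal1 differed by 2.29 (SE 0.33, adjusted p = 9.77e-04), Npas2 by 1.63 (SE 0.31) and Clock by 0.64, and Dbp by -2.09 (SE 0.29), Per3 by -2.21 (SE 0.32), Per1 by -1.31 (SE 0.19) and Tef by -0.78. Per2 (-0.98, adjusted p = 0.0550), Usp2 (-0.90, 0.0578), Nr1d1 (-0.27) and Cry1 (0.07) did not pass. Sult2a1 (3.79, SE 0.79), Akr1b7 (3.08, SE 0.64), Idi1 (3.05, SE 0.62), Msmo1 (3.04, SE 0.66) and Afp (-2.37, SE 0.29) passed, and Sds (-2.18, SE 0.57) is lost without day 21 control A, day 21 IPCR A, day 21 IPCR B or day 450 control C (0.0575 to 0.0747). Akr1b7 stood at 5.81 to 6.095 in day 450 controls, dim enough to be background, so a fall at that age could hardly be seen. Nfil3 (0.66) is lost without any of 8 arrays (0.0557 to 0.119), Wee1 (-0.95) of 8 (0.0541 to 0.0714) and Nr1d2 (-0.52) of 6 (0.0513 to 0.0646).

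Cholesterol synthesis had 16 of 20 genes with a more positive effect at day 450, or 19 over the list alone (1.52, adjusted p = 4.21e-15; adjusted p = 0.379 with an estimated correlation), and fatty acid synthesis 7 of 19, or 14 (0.98, 3.52e-06; adjusted p = 0.379 with an estimated correlation). In the PER/DBP list 6 of 12 were more negative, or 8 (-0.84, 8.53e-07; adjusted p = 0.379 with an estimated correlation), and in the BMAL1 list 4 of 5 more positive (0.66, 7.91e-04; adjusted p = 0.0990 with an estimated correlation). More positive too were endothelial markers in 3 of 7, or 6 (0.67, 3.98e-04; adjusted p = 0.379 with an estimated correlation), bile acid genes in 6 of 17, or 7 with 1 negative (0.29, 0.00201; adjusted p = 0.379 with an estimated correlation), and pericentral genes in 4 of 10, or 5 (0.54, 0.00698; adjusted p = 0.379 with an estimated correlation). Antigen presentation was more positive in 5 of 15, or 5 with 1 negative (0.30, 0.00698; adjusted p = 0.609 with an estimated correlation), the growth hormone list in 5 with 1 negative of 12, or 6 and 1 (0.47, 0.0485; adjusted p = 0.379 with an estimated correlation), with Igfals at 2.47 (SE 0.19) and Igf1 at 1.02, and the unfolded protein response in 1 of 18 (0.22, 0.0389; adjusted p = 0.854 with an estimated correlation). Fetal genes were more negative in 3 of 13 with 1 positive, or 4 and 1 (-0.24, 0.00698; adjusted p = 0.379 with an estimated correlation), with H19 at -1.98. Cholangiocyte (-0.24, 0.0470; adjusted p = 0.529 with an estimated correlation) and neutrophil markers (-0.15, 0.0470; adjusted p = 0.379 with an estimated correlation) were more negative with 1 gene each, Krt19, lost without any of 10 arrays (0.0564 to 0.0977), and Cebpe, lost without any of 4 (0.0546 to 0.0551). Of the 4 pericentral genes Cyp1a2 and Gulo are each lost without any of 5 arrays and Rhbg without any of 8 (limma adjusted p 0.0609 to 0.101). All 3 are lost without day 21 IPCR A, day 21 IPCR B or day 450 IPCR C. Eng, of the 3 endothelial genes, is lost without any of 4 arrays (0.0576 to 0.0681). The median and the mean or test differ in sign for acute phase, fatty acid oxidation, immediate early genes, B cells, T and NK cells and oxidative phosphorylation.

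In all 1189 genes differed, 951 more positive and 238 more negative, and 177 by more than 2-fold (140 and 37). This split also depends on scaling, with 80.0% positive as deposited and 52.7% after quantile normalization (778 genes, 410 and 368), 552 of them shared. With the spread of each array as a covariate, chosen after seeing the data, 112 genes differed (77 and 35). Its day 21 part uses the same 3 control arrays as the day 21 and age comparisons. Of 13 lists past camera 0 hold with an estimated correlation and 11 pass fry in 1 direction. Lists kept without each array were bile acid, cholesterol, BMAL1, PER/DBP, fetal, fatty acid synthesis, endothelial and pericentral. Antigen presentation is lost without day 21 control C, and growth hormone, cholangiocyte, neutrophil and unfolded protein lists without any of 5 to 8 arrays (0.0510 to 0.203 for all of these). The count was 781 without day 21 control A, 762 without control B, 606 without IPCR A and 712 without IPCR B, and 642 without day 450 IPCR C.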

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

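The tests of cell share for the clock and for endothelial markers, and of collection time for the clock, and the interquartile range as a covariate, were chosen only after the result was seen, and the others were set before.

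At day 21 the clock lists moved in opposite directions in IPCR, with medians of 0.76 and -0.55. A lower share of non-hepatocyte cells should move both lists as the markers moved. Medians of 11 of 11 marker lists lie between those of the 2 clock lists, a test chosen when the clock medians were known. The PER/DBP median lies well above the highest marker median, hepatocytes at 0.11, which speaks against it for that list. The BMAL1 median lies close to the endothelial median of -0.51, so for the BMAL1 list the test cannot decide. Normalization as the cause is not supported, since the gap between the clock medians was 1.33 after quantile normalization and 1.31 before. A different time of day at collection could give this pattern: 14 of 14 genes of the BMAL1 and PER/DBP lists called at day 21 moved with their list, which is consistent with a shifted phase in the liver and equally with an earlier or later collection. Collection times are not in the labels, so the time of day of each group would settle it.

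Endothelial markers fell at day 21 (median -0.51) and macrophage markers passed as a list with 0 of 11 genes passing, but with an estimated correlation neither list passes (adjusted p = 0.376 and 0.814). On the endothelial list control A stood level with IPCR A, both at -0.22 from the control mean, so the groups meet. Whether all non-hepatocyte cells had a lower share cannot be decided here. Of 6 non-hepatocyte lists 2 did not fall, cholangiocytes (0.03) and T and NK cells (0.02). But the cholangiocyte marker Cldn7 (5.72 to 5.84 in day 21 controls) is dim enough to be background and could hardly fall. Brighter members of that list could fall, such as Krt19 (7.35 to 7.56) and Krt7 (6.90 to 7.03). Krt7 differed by -0.01 (SE 0.08). Krt19 was higher by 0.61 (SE 0.17), a call lost without any of 5 arrays (limma adjusted p 0.0710 to 0.156). For T and NK cells the median and the mean or test differ in sign. Array scaling could account for part of the endothelial fall: the endothelial median was -0.34 after quantile normalization against -0.51 before, and the list still passed. The result may reflect fewer endothelial cells or lower expression in each, and the cause was not tested further. Cell counts on sections of the same livers would separate these.

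The effect of IPCR differed by age in 1189 genes. Maternal restriction ran to postnatal day 21, so it was just ending for the day 21 rats and long past for the day 450 rats. An effect of age cannot be told apart from one of time since restriction. Genes with a more positive effect at day 450 were Sult2a1 (3.79), Akr1b7 (3.08), Idi1 (3.05), Nrep (3.05) and Msmo1 (3.04), and genes with a more negative one were Igfbp2 (-3.39), Lpl (-3.00), Afp (-2.37), Per3 (-2.21) and Sds (-2.18). Akr1b7 was dim enough to be background in day 450 controls (5.81 to 6.095), so a fall at that age could hardly be seen. Lists with a positive difference were cholesterol synthesis (1.52), fatty acid synthesis (0.98), endothelial markers (0.67), BMAL1 (0.66), pericentral genes (0.54), the growth hormone list (0.47), antigen presentation (0.30), bile acid genes (0.29) and the unfolded protein response (0.22). Those with a negative difference were PER/DBP (-0.84), fetal genes (-0.24), cholangiocyte markers (-0.24) and neutrophil markers (-0.15), and 0 of these 13 lists hold with an estimated correlation. When both ages were regrouped, 1 of 100 groupings reached the real count of 1189, and the highest other count was 537. The 9 others that keep the real day 21 groups gave 182 to 537, so part of the count follows from day 21 alone. With the interquartile range of each array as a covariate 112 genes differed by age, and under quantile normalization 778, so array-wide spread could account for part of it. The covariate partly follows the groups and costs precision, and the cause was not tested further.

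Among 13905 probe sets with no symbol or several, 248 changed at day 21 in IPCR (71 higher, 177 lower) and 678 with age (221 higher, 457 lower). At day 450 29 changed in IPCR (5 higher, 24 lower), 3 in IUCR (2 higher, 1 lower) and 0 between them, and 250 differed by age (135 more positive, 115 more negative). They were not assigned to genes here, and the cause was not tested.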

How the results depend on the processing

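The interquartile range of each array as a covariate was chosen only after the result was seen. All other alternatives were set before.

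Under quantile normalization the IUCR lists past camera fell to 5 and the genes changed at day 450 were 3 for IPCR and 0 for IPCR against IUCR, and 778 genes differed by age. With arrays centred on their median 14 genes passed for day 450 IPCR and 3 for IPCR against IUCR. Among genes above the median level 9 lists passed for day 21 IPCR, 4 lists for IUCR, 17 genes and 4 lists for day 450 IPCR, and 6 lists for the difference by age. With trend and robust moderation 15 genes passed for day 450 IPCR and 1 for IPCR against IUCR. With only the groups compared 17 lists passed for IUCR, and 2 genes for day 450 IPCR and 0 for IPCR against IUCR. At adjusted p below 0.10 these were 69 and 10, with 2009 genes differing by age.

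With the interquartile range as a covariate 0 genes and 8 lists passed for day 450 IPCR, 3 genes for IPCR against IUCR and 112 genes for the difference by age (77 positive, 35 negative), against 1063 genes at day 21 (413 higher, 650 lower). The range partly follows the groups, so the covariate may remove real change.

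With an estimated correlation 0 lists passed for day 21 IPCR, 0 for IUCR, 0 for day 450 IPCR, 0 for IPCR against IUCR and 0 for the difference by age, and 6 for age. In fry 0 lists passed for IUCR, 1 for day 450 IPCR and 0 for IPCR against IUCR. In its mixed form 23 passed for day 21 IPCR, 0 for IUCR, 2 for day 450 IPCR, 4 for IPCR against IUCR and 26 for age.

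With the replicate letter as a block 0 genes passed for day 450 IPCR, 3 for IPCR against IUCR, 1291 for day 21 IPCR and 1340 for age. After removing group means, pairs of arrays with the same letter correlated at -0.26 to 0.20 (median -0.0107, 30 pairs) and pairs with other letters at a median of 0.00792 (60 pairs), so letters do not pair samples.

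Signs turned mainly at day 450 IPCR, where no clock gene passed. Under quantile normalization Per3 was -0.0726, Dbp -0.0470, Tef -0.0720 and Nfil3 -0.00144, and the list of oxidative phosphorylation -0.00948. The unfolded protein response kept a median of 0.00918 there with its test turned. Its median turned to -0.00642 for the difference by age. Among genes above the median level the PER/DBP list had a median of 0.10 with its test turned. With the covariate the PER/DBP list was -0.11, Per1 -0.0498, Per2 -0.13, Per3 -0.13, Nr1d2 -0.0252, Dbp -0.0918, Tef -0.15, Usp2 -0.23 and Cry2 -0.0699, and Cry1 was -0.13 for the difference by age.

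When each array was left out in turn, genes changed ran from 755 to 1500 for day 21 IPCR, 0 to 2 for IUCR, 0 to 80 for day 450 IPCR, 0 to 14 for IPCR against IUCR, 1025 to 1164 for age and 606 to 1546 for the difference by age. Lists ran from 10 to 15, 6 to 15, 10 to 22, 8 to 14, 15 to 18 and 9 to 14 in the same order. The correlation of the day 450 effects ran from 0.448 to 0.669.

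Values whose sign turned without 1 array ran as follows. For day 21 IPCR Bhlhe40 ran from -0.20 to 0.36 and Bhlhe41 from -0.0288 to 0.24. For age Per1 ran from -0.11 to 0.18 and antigen presentation from -0.0288 to 0.30. For day 450 IPCR Per1 ran from -0.0358 to 0.10, Per2 from -0.0523 to 0.36, Per3 from -0.0626 to 0.19, Tef from -0.0327 to 0.17, Blnk from -0.28 to 0.000763, Cela1 from -0.00411 to 0.35, Cela2a from -0.00611 to 0.53, Ctrb1 from -0.0819 to 1.08 and the acinar list from -0.0932 to 0.92. Others there kept their sign over the arrays, with Cry2 at 0.05 to 0.29, Dbp 0.01 to 0.27, Nfil3 0.02 to 0.24, Nr1d2 0.06 to 0.21, Usp2 0.01 to 0.38, the PER/DBP list 0.02 to 0.24, oxidative phosphorylation 0.07 to 0.18 and the unfolded protein response 0.10 to 0.18. For IPCR against IUCR Bhlhe40 ran from -0.18 to 0.0519 and Clock from -0.15 to 0.0647, and the acinar list stayed positive at 0.0249 to 1.05 while its test turned. For the difference by age Cry1 ran from -0.000399 to 0.22, and the unfolded protein response stayed positive at 0.15 to 0.26.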

Other observations

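The test of clock levels against the older controls was chosen only after the result was seen, as was the interquartile range as a covariate, although what it should show was written before it was run, and the regroupings were set before.

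At day 21 IPCR livers had clock gene levels nearer to those of old controls than to those of their own controls: this held for 13 of 14 called genes of the BMAL1 and PER/DBP lists, for Per1 only barely. Bmal1 was lower by 2.07 (log2) in IPCR at day 21 and by 2.48 in control at day 450, both against the same day 21 controls. One hypothesis is that restriction changes when the young clock is read, and another is that the 3 day 21 control rats were taken at another time of day than the rest, which could give both changes at once. The shared controls could produce the 13 of 14 without any restriction effect. The 14 genes were also chosen because they were called against those day 21 controls, which favours such a result. Collection times or a day 21 series over 24 hours would separate these.

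Low Igf1, Ghr and Igfals with high Igfbp2, and high Sds and Got1 with low sterol and fatty acid synthesis, appear in the same day 21 IPCR livers. These genes move as in fasting, where insulin is low and amino acids feed glucose production. Others do not: fatty acid oxidation genes had 7 falling and 1 rising, with Pdk4 at -1.37 and Bdh1 at -0.65, and the gluconeogenesis list did not pass (camera adjusted p = 0.0737). Fatty acid oxidation was not called as a list, and its member Cpt1a was higher, at 11.439 to 11.517 against 10.825 to 10.933 in control. The cholesterol list differed between rats, at -1.84, -1.66 and -0.58, and Cyp51 stood at 8.36, 8.82 and 10.85 on arrays A, B and C against 11.78 to 12.05 in control, so feeding state may have differed between the 3 rats. A measure of stomach content or plasma insulin would test this.

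At day 450 16 lists passed camera in IPCR, but 0 with an estimated correlation and 1 in fry. Array-wide spread may account for part of this: 6 of 16 lists stay called with the interquartile range as a covariate: acute phase, gluconeogenesis, adipocyte, cholangiocyte, macrophage and periportal. That range was 2.36, 2.29 and 2.45 in IPCR and 2.31, 2.27 and 2.19 in control, so the covariate partly follows the group and costs precision. Under quantile normalization, which evens out the spread directly, 11 lists passed, 9 of them among the 16, so how much is due to spread stays open. Samples from more litters would decide whether the lists differ.

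All 9 acinar genes were higher on array IPCR C at day 450 than on the other 14 arrays, with Cpa1 at 8.60 against 5.57 to 6.09. Pancreatic tissue taken with this liver would give that pattern, and without the array the list median is -0.09. The cause was not tested.

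Regrouping 3 against 3 arrays gives 10 splits, too few for a share under 0.05. At day 21 1 of 10 reached the real count (1396, highest other 0), and for age 1 of 10 (1434, highest other 1). For day 450 IPCR it was 1 of 10 (5, highest other 2), for IPCR against IUCR 1 of 10 (6, highest other 4) and for IUCR 10 of 10 (0, highest other 11).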
